A study of Homo sapiens with 4 samples.

How the data were processed

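RNA was measured in NCI-H292 cells, an established human airway epithelial line that came from a mucoepidermoid carcinoma of the lung. Per the labels, confluent cultures received vehicle or a commercial extract of Aspergillus fumigatus, Penicillium notatum or Alternaria alternata at 1000 protein nitrogen units per ml, and RNA was taken after 24 h. Cultures that received Candida albicans extract, which the labels' protocol also names, were not analysed here. Each of the 4 groups held 1 array, so no spread between cultures could be estimated, and no test and no p-value was computed. The descriptions of the P. notatum and A. alternata samples name other cell-line numbers than the cell line field, which gives NCI-H292 for all 4, and the cell line field was followed.

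The deposited scanner files hold linear spot intensity from 1-colour arrays with 45015 spots each, labelled with Cy3. Per the file headers the images were read with Agilent Feature Extraction 10.5.1.1 on array design 014850 with hg18 annotation, and the submitters' processing notes name version 10.5. Per the file headers, the processed intensity had the local background subtracted and spatial trends removed within each array, and was not scaled between arrays. The 4 arrays lay on 1 slide, at places 1 (vehicle), 2 (A. fumigatus), 3 (P. notatum) and 4 (A. alternata), and shared 1 scan. The authors also deposited a table of linear ratios of each extract over vehicle, with 41059 rows. The last 59 rows of it repeated the values of the rows before them shifted by 1 column and were left out. Over probes well above background, the log2 of the deposited ratios differed from the scanner difference by a nearly constant offset, of 0.91 for A. fumigatus, -0.036 for P. notatum and -0.16 for A. alternata (SD 0.0011, 0.0026 and 0.0028). This offset fixes the direction of the ratios as extract over vehicle, and the scaling step behind it is not given in the sources used here.

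Control spots and spots marked as non-uniform or as population outliers were left out, and 0 spots were saturated. Repeated spots of a probe were averaged. The processed intensity was put on the log2 scale and the 75th percentile of each array over the non-control probes was subtracted. A fold is therefore relative to the upper range of its own array. Of 41000 probes, 24794 were named through their RefSeq accession, compared without version numbers with a RefSeq gene table of assembly GRCh38.p14, which gave 16961 symbols. The other 16206 probes had no name here and entered no gene count. The table served for names alone, and no coordinates are given because the array annotation uses an older build. Among the 6040 genes with several probes, the probe with the highest mean signal over the 4 arrays stood for the gene. A gene counted as measured in a comparison when this probe was well above background, in the scanner software's own call, on both arrays. When it was well above background on 1 array alone, the brighter value was set against the higher of the dim probe's own signal and the lowest signal among probes well above background on the dim array, and the fold is given as "at least". No such fold is given where the bound came to less than 1. These bounds rest on the scanner software's background-subtracted signal, carry no spot error and are not given under the alternatives below.

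Genes were counted at 2-fold or more. The comparisons were each extract against vehicle, each pair of extracts, and genes 2-fold or more apart from all 3 other arrays in 1 direction. For each of 27 gene lists with 3 or more measured members, the median log2 difference was placed among 10000 random lists of the same size matched on mean signal in 20 bins. The resulting percentile describes these arrays and is no test. Of 575 list memberships 555 had a named probe, and those without one, the mucins MUC5AC and MUC5B among them, were not analysed here. Technical error came from 264 probes printed in 10 spots each. The median SD of their log2 signal was 0.028 on the vehicle array, 0.0448 on the A. fumigatus array, 0.0281 on the P. notatum array and 0.0289 on the A. alternata array, over 214, 206, 220 and 214 of them well above background. The spot error of a gene is the SD expected for a difference of the 2 arrays at its signals. It leaves out all variation between cultures, labellings and hybridisations.

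The lists, thresholds, settings to vary and the rule for named genes were fixed before the data were examined. That rule took, per extract, the 10 genes with the largest log2 difference in each direction, up to 3 lower-bound folds per direction, up to 4 members of each list with the largest absolute difference, 5 genes per direction apart from all other arrays for A. fumigatus, and MUC5AC, EGFR, AREG, TGFA, HBEGF, EREG, CXCL8, ACTB and GAPDH in every comparison. Clone, locus and open reading frame names were passed over, and values of some single genes that the rule takes are not reported here. Alternatives were normexp background correction with an offset of 50, quantile normalization, cyclic loess, a median centre, a scale from 7 spike-in probes, no filter on dim probes, a filter on all 4 arrays, a mean over probes, thresholds of 1.5-fold and 3-fold, and the authors' deposited ratios. A minimum signal of 100 on both arrays was added after the data were seen. The plan had assumed symbols and mean spot signals in the scanner files. These hold neither, so symbols came from accessions and normexp was run on median spot and background signals. The normexp offset of 50 is added to every signal, so it shrinks the folds of dim genes by construction.

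The counting step was tested on simulated arrays. Of genes simulated at 3-fold and measured, 100% were called in each comparison with vehicle (90 of 90 for A. fumigatus, 92 of 92 for P. notatum and 91 of 91 for A. alternata). At a simulated 1.5-fold, 0 of 91, 0 of 98 and 0 of 98 were called at the 2-fold threshold. Of the unchanged genes, 0 of 12052, 0 of 12734 and 0 of 12685 were called. These simulations carry spot error alone. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.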

Results

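Gene expression was measured once per stimulus in NCI-H292 airway epithelial cells after 24 h with vehicle, A. fumigatus extract, P. notatum extract or A. alternata extract. The question was which genes each fungal extract changes in airway epithelium, and which of them are particular to A. fumigatus. With 1 array per group and no replicates, every difference below is a difference between 2 arrays. Differences are given as log2 of extract over vehicle, and the spot error quoted with some is technical only. The 75th percentile of the spot signal was 800 on the vehicle array, 420 on the A. fumigatus array, 854 on the P. notatum array and 882 on the A. alternata array. The A. fumigatus array thus had 52.5% of the brightness of the vehicle array, and its spike-in probes, which are added in known amounts at labelling, had 51.0%. Of 41000 probes, 27912, 25623, 27806 and 27931 were well above background on the 4 arrays.

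The A. fumigatus extract came with higher levels of genes that respond to growth factor signalling, of cell cycle genes and of amino acid supply genes. IER3, an early response gene, was 13.7-fold higher (log2 3.77, spot error 0.038), and SERPINE2, which inhibits serine proteases, was 33.2-fold higher (5.05, spot error 0.17). DEFB1, which encodes the antimicrobial peptide beta-defensin 1, was 26.3-fold lower (-4.72, spot error 0.047). MMP1, the interstitial collagenase, was not well above background with vehicle and was at least 140-fold higher, a bound given under the main processing alone. Of 12321 measured genes, 966 were at least 2-fold higher and 604 at least 2-fold lower, and 125 and 88 passed 4-fold.

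Besides SERPINE2 and IER3, the measured genes with the largest positive differences were ACOX2, an enzyme of peroxisomal bile acid synthesis (6.18), HORMAD2 (4.30), the secreted trefoil peptide TFF1 (4.28), EMP3 (3.84), the neuropeptide gene GAL (3.76), the mucosal scavenger protein gene DMBT1 (3.66), GINS4, part of the replication helicase (3.52), and the keratin gene KRT6B (3.49). At the other end stood KANK4 (-4.48), the ubiquitin-like modifier UBD (-4.39), the immune checkpoint ligand VTCN1 (-4.14), VGLL1 (-3.70), the transcription factor MAF (-3.53), the scaffold protein NEDD9 (-3.51), the collagen gene COL12A1 (-3.37), CLIC3 (-3.35) and ASPA (-3.29). ACOX2, HORMAD2, EMP3 and KRT6B had vehicle signals of 25.1, 14.7, 23.3 and 26.9, near the background limit, with spot errors of 0.174 to 0.181, and SERPINE2 one of 34.5. KANK4, NEDD9, CLIC3 and ASPA had signals of 18.4, 18.3, 18.2 and 18.5 with the extract, also near that limit. Under normexp background correction the folds were over 1.5 times smaller for SERPINE2 (3.51), ACOX2 (4.26), HORMAD2 (2.33), TFF1 (3.54), EMP3 (2.31), GINS4 (2.40) and KRT6B (2.10). The same held for KANK4 (-2.59), UBD (-3.47), VTCN1 (-3.39), VGLL1 (-2.62), MAF (-2.79), NEDD9 (-1.67), CLIC3 (-1.55) and ASPA (-1.50). A second TFF1 probe stood at 2.73. IL1R2, a decoy receptor for interleukin 1, was at least 52.4-fold higher and MYH13 at least 29.5-fold higher, whereas PSG8, SEMA6D and ERP27 were at least 12.8-fold, 12.3-fold and 12.2-fold lower.

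Of 19 measured ERK-responsive genes, which are induced or act as feedback below the MAP kinase ERK, 11 were at least 2-fold higher and 0 lower, with a median of 1.04. DUSP6 (2.99) and DUSP4 (2.21), phosphatases that switch off MAP kinases, and the AP-1 gene JUN (2.16) were among them. The EGFR list was split. Its ligand genes HBEGF (2.31) and AREG (1.28) and the EGFR inhibitor gene ERRFI1 (2.28) were higher, whereas EGFR itself stood at -0.44, ERBB2 at -0.83 and TGFA at 0.41. The median over its 11 measured members was -0.10 and the mean 0.27, which differ in sign. EREG was not well above background on either array, and neither was CXCL8.

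Cell cycle genes were higher as a group. Of 37 measured S phase and mitosis genes, 23 were at least 2-fold higher and 0 lower (median 1.09), led by RRM2, which makes deoxynucleotides (2.76), the replication factors MCM10 (2.07) and CDC6 (2.04), and E2F1 (1.93). Of 18 amino acid and ATF4 response genes, 10 were at least 2-fold higher and 0 lower (median 1.06). They included the cystine transporter SLC7A11 (2.39), the serine synthesis enzyme PSAT1 (2.08), asparagine synthetase ASNS (1.68) and the glutathione-degrading enzyme CHAC1 (1.41). Of 20 NRF2 and oxidative stress genes, 4 were at least 2-fold higher and 0 lower (median 0.65), among them the aldo-keto reductase AKR1C1 (3.41) and the transporter ABCC3 (2.26). AKR1C1 has near-identical relatives that its probes may also read. Of 11 xenobiotic genes 4 were higher and 0 lower (median 0.77), with CYP1B1 8.02-fold higher and ALDH1A3 at a log2 of 1.67. Cholesterol synthesis and uptake genes had a median of 0.42, with 2 of 24 at least 2-fold higher, MSMO1 (1.08) among them, and 0 lower. The hypoxia and glycolysis list had a median of 0.50, with 7 of 27 higher and 0 lower, among them ANGPTL4 (3.36), ENO2 (2.92), CA9 (2.46) and VEGFA (1.36).

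Of 16 secretory and goblet cell genes 7 were at least 2-fold higher and 0 lower (median 0.78), including TFF1, the goblet cell transcription factor SPDEF (2.62), the mucin glycosyltransferase GCNT3 (2.50) and TFF2 (1.43). Of 6 measured mucins, MUC6 was at least 2-fold higher (1.08) and MUC20 at least 2-fold lower (-1.84), and the median was 0.12, against -0.46 with the mean over probes and 0.60 with no filter on dim probes. The squamous list held 6 higher genes, among them KRT6B and S100A9 (2.07), and 2 lower ones, KRT4 (-2.93) and KRT13 (-1.93), of 18 measured. In the plasminogen and protease list 6 of 17 were higher and 1 was lower. The urokinase receptor gene PLAUR (2.14) and the tissue plasminogen activator gene PLAT (1.47) were higher, and the urokinase gene PLAU was lower (-1.42).

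Inflammatory genes did not share a direction. Among 18 measured cytokines and chemokines, 6 were at least 2-fold higher and 1 was lower (median 0.67), with IL23A (2.17), IL1A (2.12) and TSLP (1.42) higher and the mucosal chemokine CCL28 lower (-1.97). Of 15 NF-kappaB feedback genes 1 was higher, BCL3 (1.34), and 1 lower, TNFAIP2 (-1.37), with a median of -0.30. Of 23 interferon-response genes 3 were higher, OAS1 (2.17), OAS3 (1.91) and OASL (1.62), and 3 were lower, STAT2 (-1.24) among them, with a median of -0.42. Among random lists of matched signal, the S phase and mitosis, ERK, ATF4 and NRF2 medians stood at the 100th percentile, the cytokine median at the 99.7th, the NF-kappaB median at the 3.27th and the interferon median at the 0.19th. With a signal of at least 100 on both arrays the interferon median was -0.13, at the 27.4th percentile, and with no filter on dim probes -0.11, at the 12.2th. Under normexp ANGPTL4 stood at 2.63, ENO2 at 1.92 and IL1A at 1.43, over 1.5 times smaller, and CCL28 at -0.39, STAT2 at -0.48, MUC6 at 0.89, TFF2 at 0.97 and MSMO1 at 0.98, the last 5 under 2-fold. Of the reference genes, ACTB stood at -0.15 and GAPDH at 0.50.

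Part of the higher count lay near the 2-fold threshold, with a raw signal little above that with vehicle. Of the 966 higher genes, 415 (43.0%) had a raw signal less than 1.25-fold above that with vehicle. Such a share follows from scaling an array with 52.5% of the vehicle brightness. It cannot tell residual background from a true rise, since the spike-in probes also had 51.0%. Of 46 measured genes of families mostly used by other tissues, picked after the result was seen, 23 were at least 2-fold higher on this array. This pick does not stand for all dim genes. The dimmest tertile of measured genes had a median of 0.10, though 827 of the 1570 calls lay in it. Of 16 secretory genes 7 were at least 2-fold higher. Over those with a signal of at least 100 on both arrays the median was 0.93, against 0.78. Other list medians moved either way under that limit. The cytokine median went from 0.67 to 0.74, the squamous median from 0.62 to 0.41 and the protease median from 0.75 to 0.59. With a signal of at least 100 on both arrays, a limit chosen after the data were seen, 537 genes were higher and 374 lower.

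**Figure D1:**
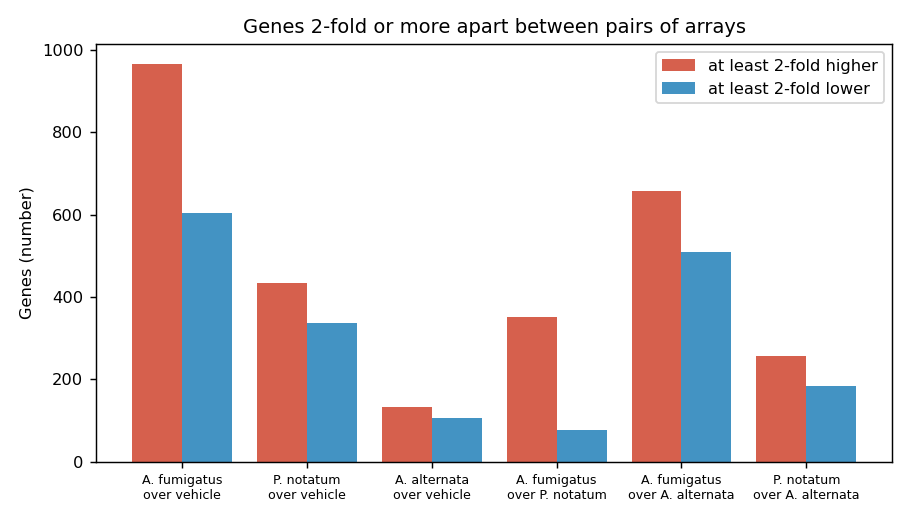
Bars give the number of genes at least 2-fold higher (red) or lower (blue) on the first array than on the second, for each pair of arrays named under the bars, 1 array per group. The A. fumigatus array against vehicle has 966 and 604 genes, P. notatum 434 and 336, and A. alternata 134 and 107.

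With the P. notatum extract SERPINE2 was 22.9-fold higher (4.52, spot error 0.167), the serum response gene FOSB 14.4-fold higher (3.85, spot error 0.175), and CBS, which makes cystathionine from homocysteine, 13.9-fold higher (3.80, spot error 0.04). CLIC3 was 13.1-fold lower (-3.71, spot error 0.144) and DEFB1 7.50-fold lower (-2.91, spot error 0.026). Of 12707 measured genes, 434 were at least 2-fold higher and 336 at least 2-fold lower, and 49 and 28 passed 4-fold.

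ACOX2 (4.42), AKR1C1 (3.66), TFF1 (3.04), KRT6B (2.91), GAL (2.89), the carbonic anhydrase gene CA12 (2.89) and EMP3 (2.87) completed the 10 largest positive differences. PSG8, a pregnancy-specific glycoprotein gene with near-identical relatives (-3.49), ACSS1 (-3.48), GUCY1B2 (-3.03), the Mediator subunit gene MED18 (-3.02), ZG16 (-2.93), KANK4 (-2.84), PCDHB9 (-2.76) and the proton pump gene ATP6V1B1 (-2.59) completed the negative ones. ACSS1, MED18 and ZG16 had signals of 19.0, 18.2 and 18.4 with the extract, close to background. FOSB and SERPINE2 had vehicle signals of 15.9 and 34.5. Under normexp the folds were over 1.5 times smaller for SERPINE2 (3.08), FOSB (1.89), ACOX2 (2.68), TFF1 (2.45), KRT6B (1.46), EMP3 (1.51), CLIC3 (-2.20) and PSG8 (-2.22). So they were for ACSS1 (-1.62), GUCY1B2 (-1.79), MED18 (-1.42), ZG16 (-1.25), PCDHB9 (-1.82) and ATP6V1B1 (-1.43). Second probes of PCDHB9 and TFF1 stood at -0.73 and 1.51. MMP1, MYH13 and the epithelial transcription factor KLF4 were at least 18.1-fold, 15.3-fold and 10.9-fold higher, and PSG6 was at least 22.3-fold lower. CXCL8, the neutrophil chemokine, was at least 2.42-fold higher and EREG at least 1.64-fold higher, both from a vehicle signal not well above background.

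Of 19 ERK-responsive genes 9 were at least 2-fold higher and 0 lower (median 0.94), with IER3 (2.73), DUSP6 (2.65) and EGR1 (2.31) besides FOSB. HBEGF (1.84), ERRFI1 (1.76) and AREG (1.74) were higher, whereas EGFR stood at -0.22, ERBB2 at -0.88 and TGFA at -0.04. The median of the 11 measured members of that list was -0.04 and the mean 0.30, again of opposite sign. Of 37 S phase and mitosis genes 14 were at least 2-fold higher and 0 lower (median 0.90), with RRM2 (1.95), CDC6 (1.81), MCM10 (1.73) and E2F1 (1.64) in front. Of 18 ATF4 response genes 8 were higher and 0 lower (median 0.93), including PSAT1 (2.22), SLC7A11 (2.21), ASNS (1.95) and the serine synthesis enzyme PHGDH (1.31). Of 20 NRF2 genes 7 were higher and 0 lower (median 0.65), including ABCC3 (2.42), AKR1C3 (1.93) and the glutathione synthesis gene GCLM (1.32). Of 11 xenobiotic genes 5 were higher and 1 was lower (median 0.92), with CYP1B1 at 2.58 and CYP3A5 at -1.17. Cholesterol genes had a median of 0.25 and 1 of 24 at least 2-fold higher, with DHCR7 at 0.64 and SQLE at 0.62. Hypoxia and glycolysis genes had a median of 0.22, with 3 of 27 higher and 1 lower, the glucose transporter gene SLC2A3 (-1.98).

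Cytokines again went both ways, with 7 of 21 measured genes at least 2-fold higher and 2 lower. Their median of 0.43 stood at the 99.99th percentile of random lists, with 12 genes above 0 and 9 below. IL1A (1.93), CCL20, which attracts dendritic and T cells (1.76), and TSLP (1.69) were higher and CCL28 was lower (-1.73). None of 15 NF-kappaB feedback genes reached 2-fold in either direction (median 0.02), with BCL3 at 0.95 and BIRC3 at 0.70. Of 24 interferon-response genes 2 were higher, OAS1 (1.64) and OAS3 (1.58), and 1 was lower, IFIT1 (-1.10), with a median of -0.11. Among secretory genes 4 of 16 were higher and 1 lower, with GCNT3 at 2.71, SPDEF at 1.85 and FUT2 at -1.01, and the median was 0.08. That median ranged from -0.05 to 0.47 over the alternatives, with 0.47 at a signal of at least 100. MUC20 was lower (-1.12) and the other 5 measured mucins lay within 2-fold. In the squamous list 5 of 18 were higher, S100A9 (2.23) among them, and 2 were lower, KRT13 (-2.32) and KRT4 (-2.21), with a median of 0.04. In the protease list PLAT (1.36), PLAUR (1.34) and SERPINB4 (1.15) were higher, 6 of 18 in all with 0 lower. The ERK, S phase and mitosis, ATF4, NRF2 and xenobiotic medians stood at the 100th percentile of random lists, the NF-kappaB median at the 53.8th and the interferon median at the 10.6th. Under normexp HBEGF stood at 1.20, IL1A at 1.08 and SLC2A3 at -1.19, over 1.5 times smaller, and FUT2 at -0.38, CCL20 at 0.71, IFIT1 at -0.89, CCL28 at -0.90 and CYP3A5 at -0.99, the last 5 under 2-fold, and the cytokine median was 0.20. ACTB stood at -0.62 and GAPDH at 0.09.

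The A. alternata extract came with fewer and smaller differences. IL6, an acute-phase cytokine, was 7.13-fold higher (2.83, spot error 0.18) from a vehicle signal of 20.3, near background, and stood at 1.25 under normexp. CBS was 5.91-fold higher (2.56, spot error 0.043) and SERPINE2 5.20-fold higher (2.38, spot error 0.17, and 1.28 under normexp). CYP1A1, the classic target of the aryl hydrocarbon receptor, was at least 26.3-fold higher. KIF20A, a kinesin needed for cell division, was 5.51-fold lower (-2.46, spot error 0.09). Of 12755 measured genes, 134 were at least 2-fold higher and 107 at least 2-fold lower, and 10 and 8 passed 4-fold.

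The other large positive differences were KRT6B (2.49), EDIL3 (2.31), the adhesion molecule gene CEACAM1 (2.23), SAA4 (2.18), the pantetheinase gene VNN1 (2.17), CYP1B1 (2.05) and ABCC3 (2.03). A second CEACAM1 probe stood at 0.30. Besides KIF20A, the largest negative differences were RALGAPB (-3.24), APOL6 (-3.23), ACTL7B (-2.69), HSPB3 (-2.59), PLEKHA2 (-2.37), NUTM2A (-2.22) and the pregnancy-specific glycoprotein genes PSG9 (-2.08), PSG8 (-1.97) and PSG4 (-1.97). The APOL6 value rests on 1 probe, since other probes of the gene stood at -0.60 and 0.16. ACTL7B, HSPB3, EDIL3 and SAA4 had a signal under 20 on 1 of their 2 arrays. Under normexp the folds were over 1.5 times smaller for KRT6B (1.14), CEACAM1 (1.17), VNN1 (1.09), ACTL7B (-1.12), HSPB3 (-1.23), PLEKHA2 (-1.51), NUTM2A (-1.19) and PSG9 (-1.04). NR2E1 and TNFRSF19 were at least 10.2-fold and 9.08-fold higher, and CXCL8 was at least 4.19-fold higher. EREG was not well above background on either array.

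Of 21 measured cytokines and chemokines 6 were at least 2-fold higher and 0 lower (median 0.37), including IL1A (1.99), CCL20 (1.98) and the neutrophil chemokine CXCL1 (1.45). Their median was 0.18 with a signal of at least 100 and 0.16 with no filter on dim probes. None of 15 NF-kappaB feedback genes reached 2-fold, yet 14 of them lay above 0 and their median of 0.49 stood at the 100th percentile of random lists. Members were BIRC3, an inhibitor of apoptosis (0.95), the feedback gene TNFAIP3 (0.78), the superoxide dismutase gene SOD2 (0.75) and BCL3 (0.68). None of 24 interferon-response genes reached 2-fold (median 0.11), with HERC5 at 0.75 and SAMD9 at -0.62.

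Of 37 S phase and mitosis genes 1 was at least 2-fold higher and 5 were lower, with a median of -0.29 at the 0th percentile. The lowest were KIF20A, the mitotic kinase PLK1 (-1.89), the kinetochore motor CENPE (-1.38) and CDC20, which drives the exit from mitosis (-1.25). Cholesterol genes had a median of -0.22, at the 0.01th percentile, with IDI1 at -0.62 and 0 of 24 at 2-fold. ERK-responsive genes had a median of 0.62 with 3 of 19 at least 2-fold higher and 0 lower, IER3 (1.49), DUSP6 (1.17) and FOSL1 (1.02). AREG (0.91), HBEGF (0.83), EGFR (0.07) and TGFA (-0.45) all lay within 2-fold. Of the ATF4 genes 3 of 18 were higher and 0 lower (median 0.54), SLC7A11 (1.58), PSAT1 (1.48) and ASNS (1.07). Of the NRF2 genes 4 of 20 were higher and 0 lower (median 0.47), with AKR1C1 at 1.68, the haem oxygenase gene HMOX1 at 1.30 and the ferritin gene FTL at 1.15. Xenobiotic genes had a median of 0.56, with 1 of 11 higher, CYP1B1, and 1 lower, CYP3A5 (-1.44).

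Of 16 secretory genes 1 was higher, GCNT3 (1.40), with a median of 0.21. None of 7 measured mucins reached 2-fold, and MUC1 stood at 0.81. In the squamous list 3 of 18 were higher, KRT6B, S100A8 (1.51) and S100A9 (1.45), and 3 were lower, KRT13 (-1.71) among them. The hypoxia and glycolysis list had a median of -0.01, with 0 of 27 higher and 1 lower, SLC2A3 (-1.16, and -0.86 under normexp). In the protease list 1 of 18 was higher and 0 lower (median 0.08). Under normexp IL1A stood at 1.11, and FOSL1 at 0.28, SAA4 at 0.69, EDIL3 at 0.73, DUSP6 at 0.80, CCL20 at 0.91 and PSG4 at -0.97, the last 6 under 2-fold. ACTB stood at -0.61 and GAPDH at 0.15. Many of the counted genes of this extract were dim, since with a signal of at least 100 on both arrays 62 genes were higher and 68 lower. Under normexp background correction the counts were 53 and 58. It also started from median spot signals and its offset shrinks dim folds, and the loss was not split by signal.

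**Figure D2:**
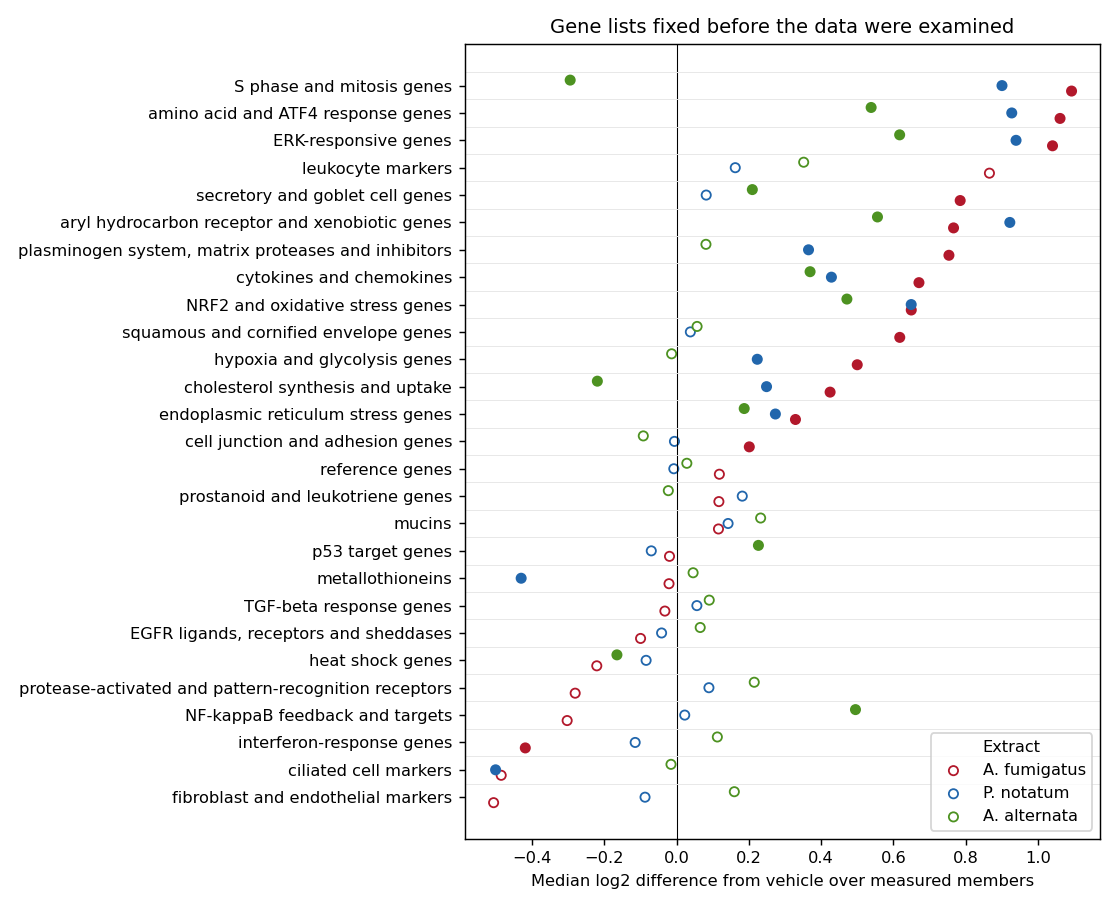
Each point is the median log2 difference from vehicle over the measured members of a gene list, for A. fumigatus (red), P. notatum (blue) and A. alternata (green). Filled points lie above the 97.5th or below the 2.5th percentile of 10000 random lists of matched signal. The S phase and mitosis list has medians of 1.09, 0.90 and -0.29 for the 3 extracts.

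Over 12285 genes measured on all 4 arrays, 944 were at least 2-fold higher and 604 lower with A. fumigatus, 425 and 267 with P. notatum, and 120 and 89 with A. alternata. Of these, 371 were higher with both A. fumigatus and P. notatum and 224 lower with both, where independent lists would share 32.7 and 13.1. For A. fumigatus and A. alternata 70 and 36 were shared (9.22 and 4.38 for independent lists), and for P. notatum and A. alternata 69 and 46 (4.15 and 1.93). At least 2-fold higher with all 3 extracts were 60 genes, and 34 were lower with all 3. SERPINE2, CBS, AKR1C1, CYP1B1, ABCC3, SLC7A11, IL1A, IER3 and KRT6B were among those higher, and KRT13 and PCDHB9 among those lower. A second PCDHB9 probe stood at -0.73 with P. notatum and -0.38 with A. alternata, within 2-fold, and was not measured with A. fumigatus.

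Across genes, which are not independent replicates, the log2 differences of A. fumigatus and P. notatum correlated with r = 0.82 (rho = 0.77). A. fumigatus with A. alternata gave r = 0.47 (rho = 0.46) and P. notatum with A. alternata r = 0.64 (rho = 0.63). All 3 comparisons share the vehicle array. Unchanged arrays simulated with spot error alone gave r of 0.52, 0.53 and 0.58, a covariance of 0.0034 for each pair, and 0 shared genes at 2-fold. The observed covariances were 0.29, 0.11 and 0.11. The simulation leaves out the spread between cultures and a single vehicle array cannot be split, so part of the overlap may come from the shared vehicle array.

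Of 12382 genes measured in both, 657 were at least 2-fold higher and 510 lower with A. fumigatus than with A. alternata. Between P. notatum and A. alternata these were 257 and 185 of 12778. Between A. fumigatus and P. notatum they were 351 and 76 of 12413, and 347 of these 427 genes lay in the dimmest tertile of signal and 26 in the brightest.

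**Figure D3:**
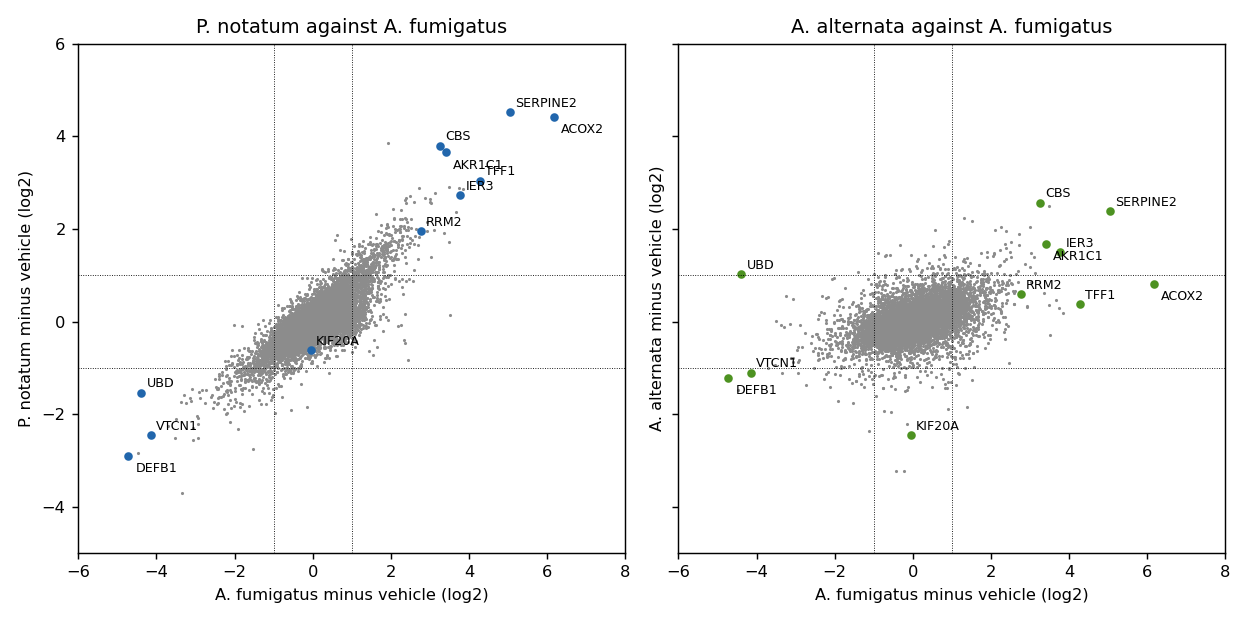
Each grey point is 1 of 12285 genes measured on all 4 arrays, at its log2 difference from vehicle with A. fumigatus (horizontal) and with P. notatum (left, r = 0.82) or A. alternata (right, r = 0.47). Coloured points carry gene names, and dotted lines mark 2-fold.

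Genes apart from all 3 other arrays by at least 2-fold numbered 187 for A. fumigatus, with 126 higher and 61 lower, 36 for A. alternata, with 11 higher and 25 lower, and 1 for P. notatum. The A. fumigatus genes with the largest smallest fold were GINS4 (10.4-fold), TRIM74 (5.40-fold), AS3MT, which methylates arsenic (5.15-fold), TM6SF2 (5.06-fold) and the smooth muscle gene SMTN (4.59-fold) on the higher side. None of these 5 had a signal of 100 on both arrays, and under normexp TRIM74, TM6SF2 and SMTN stood at 1.78, 1.39 and 1.54 against vehicle. A second GINS4 probe stood at 2.50 against vehicle. On the lower side were UBD (7.21-fold), the potassium channel gene KCNJ2 (3.84-fold), DEFB1 (3.51-fold), the glutamate transporter gene SLC1A3 (3.29-fold) and ASPA (3.28-fold). KCNJ2 stood at -0.48 against vehicle under normexp, and SLC1A3 at -1.23 with the mean over probes. UBD stood at -4.39 with A. fumigatus, -1.54 with P. notatum and 1.02 with A. alternata. DEFB1 was lower with every extract, at -4.72, -2.91 and -1.21. The 1 gene of P. notatum was FOSB, at 3.85 against 1.93 with A. fumigatus and 0.09 with A. alternata. The A. fumigatus count was 75 under normexp background correction and 62 with a signal of at least 100, and the array's own brightness goes with the group.

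The cell cycle genes divided by phase. The 16 measured S phase members had medians of 1.15 with A. fumigatus, 1.09 with P. notatum and 0.63 with A. alternata, and 16, 16 and 15 of them lay above 0. The 21 measured mitosis members had medians of 1.08, 0.61 and -0.71. With A. alternata 20 of these 21 lay below 0 and 5 were at least 2-fold lower. RRM2 stood at 2.76, 1.95 and 0.59 and PLK1 at 0.91, 0.20 and -1.89. The division of the list into phases was made after its values had been seen.

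**Figure D4:**
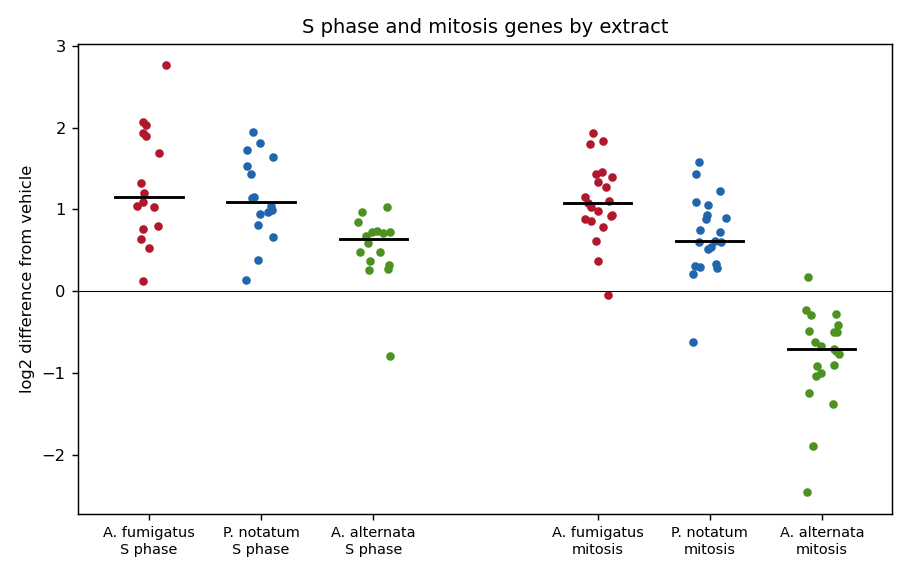
Points are the log2 differences from vehicle of the measured S phase genes (left, 16 genes) and mitosis genes (right, 21 genes) for each extract, 1 array per group, and black lines are medians. The mitosis genes lie mostly above 0 with A. fumigatus and P. notatum and mostly below 0 with A. alternata (20 of 21).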

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

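The tests of fewer cycling cells and of residual background were chosen only after the result was seen. Probes without a gene name here also differed from vehicle, and they enter no count of the report. At least 2-fold higher were 696 with A. fumigatus, 161 with P. notatum and 111 with A. alternata, and at least 2-fold lower were 514, 303 and 74.

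Some genes were at least 2-fold from vehicle in opposite directions with 2 extracts, which was not tested for lack of replicates. For A. fumigatus and A. alternata there were 8 such genes. The mitosis genes CENPE, HMMR, NEK2 and PSRC1 and the histone gene H1-5 were higher with A. fumigatus (CENPE 2.15-fold, the others at a log2 of 1.19, 1.16, 1.38 and 1.52) and lower with A. alternata (-1.38, -1.12, -1.10, -1.85 and -1.26). RARRES1 and UBD went the other way, at -1.41 and -4.39 against 1.08 and 1.02, and so did MAP3K13, 2.01-fold lower and at 1.03. For P. notatum and A. alternata there was 1 such gene, UBD (-1.54 and 1.02).

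The A. fumigatus array held the most genes at 2-fold and was also the dimmest. Low brightness as the whole cause is argued against for bright genes, since in the brightest tertile of genes measured on all arrays it still had 311 against 136 with P. notatum, 2.29 times as many. After cyclic loess, which removes trends with intensity, the ratio of the counts was 1.98. For genes near the threshold residual background on the dimmer array may add calls. Olfactory and taste receptor, hair keratin-associated and late cornified envelope genes, which are mostly used by other tissues, had a median of 0.99 over 46 measured genes at similar raw signals (101 with vehicle and 106 with the extract). These families were picked after the result was seen, and the dimmest tertile of measured genes as a whole had a median of 0.10. Place on the slide cannot be told apart from the extract, with 1 array per place, and an effect of the extract itself stays open, untested without replicates.

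Of the rows in the authors' deposited table, 9624 (23.5%) were at least 2-fold higher with A. fumigatus, and 1850 of these (19.2%) were well above background on both arrays. The values needed for signals at the scanner floor scaled up by the dimmer array were there. Probes not well above background on either array had a median log2 ratio of 1.01 over 12673 rows, against -0.018 over 25208 rows well above background on both. The likely source of the skew in that table is this scaling of floor signals, and a biological explanation was not tested.

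The mitosis genes were lower with A. alternata while the S phase genes were not. Of the 21 genes 20 (95.2%) lay below 0, and 3 of 3 second probes were also lower. Fewer cycling cells overall would lower both phases, yet the S phase median was 0.63. Scaling between arrays left the mitosis median between -0.73 and -0.66 over the scalings tried. What stays open is error of single probes, place on the slide, chance variation between cultures and an effect of the extract on the passage through G2 and mitosis, which is a hypothesis that these 4 arrays cannot test.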

How the results depend on the processing

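The minimum signal of 100 was chosen after the data were seen, and all other alternatives were planned. No paired analysis was possible because each group held 1 array, and no replicate could be left out. Of 210 alternative values of the main counts and correlations 155 stayed within 1.5 times, or within 0.1 for a correlation. The correlations could not change under the median centre, the spike-in scale and the filter on all arrays, by construction. Under the deposited ratios, which add a nearly constant shift, they could hardly change either. Quantile normalization, cyclic loess, the median centre, the spike-in scale, the filter on all arrays and the deposited ratios moved no count or correlation further. Lists with a median below the lower percentile numbered 1 with A. fumigatus, against 2 with the mean over probes, 0 with no filter on dim probes and 0 with a signal of at least 100. With P. notatum they numbered 2, against 1 under normexp and 1 with a signal of at least 100. With A. alternata they numbered 3, against 2 under quantile normalization, 2 with the mean over probes and 4 with a signal of at least 100. The heat shock median of A. alternata went from the 2.31th percentile to the 10.9th with the mean over probes. Its secretory median went from the 98.4th percentile to the 92.5th under normexp. No scaling moved the share of higher genes among calls by more than 10 percentage points or the median of all measured genes by more than 0.1. Of 233 named gene values at 2-fold or more, 2230 of 2231 alternative values kept their direction and 63 lay under 2-fold, 39 of them under normexp. Under normexp 74 of the 233 folds were over 1.5 times smaller, with the mean over probes 10, and 82 of the 233 had no value with a signal of at least 100. The exception was TLR5 with A. fumigatus, at -1.26, which reversed to 0.0033 under normexp. Its signal on that array was 16, near background and under the offset of 50 that normexp adds. Such an offset draws a fold at that signal towards 0, and other causes were not tested. For the 233 values the direction could not turn under the filters on signal, which leave a measured value unchanged. Nor could it under the median centre, the spike-in scale and the deposited ratios, which add a small, nearly constant shift.

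Counts moved as follows, given as higher and lower against vehicle for A. fumigatus, P. notatum and A. alternata, then for A. fumigatus against P. notatum, A. fumigatus against A. alternata, P. notatum against A. alternata, and A. fumigatus apart from all others. The main counts were 966 and 604, 434 and 336, 134 and 107, then 427, 1167, 442 and 187. Under normexp, which also started from median spot signals, they were 604 and 362, 261 and 173, 53 and 58, then 198, 735, 237 and 75. With no filter on dim probes they were 3748 and 918, 869 and 704, 668 and 346, then 3325, 2286, 1212 and 737, because signals at the floor enter. That setting moved the share of higher genes from 61.5% to 80.3% for A. fumigatus and from 55.6% to 65.9% for A. alternata, and the correlation of A. fumigatus with P. notatum from 0.82 to 0.66. At a threshold of 1.5-fold they were 2206 and 1707, 1159 and 1026, 633 and 431, then 1673, 3310, 1351 and 1141. At 3-fold they were 270 and 180, 135 and 80, 26 and 21, then 47, 337, 101 and 25. With a signal of at least 100 they were 537 and 374, 293 and 197, 62 and 68, then 140, 668, 264 and 62. The 1.5-fold, 3-fold and signal limits move the counts by their construction. So does the normexp offset of 50 for dim genes, whose folds it shrinks.

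Second probes of genes at 2-fold pointed the same way in 332 of 361 cases for A. fumigatus (92.0%), 179 of 189 for P. notatum (94.7%) and 55 of 62 for A. alternata (88.7%), and 78.9%, 81.0% and 62.9% of them differed by at least 1.5-fold that way. Over all alternatives the S phase and mitosis median ranged from 1.004 to 1.134 with A. fumigatus, from 0.77 to 0.96 with P. notatum and -0.32 to -0.23 with A. alternata. The NF-kappaB median with A. alternata ranged from 0.47 to 0.54. Of 81 list medians 23 had the other sign under an alternative, and 0 of these lay beyond the upper or lower percentile.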

Other observations

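ALOX5, the 5-lipoxygenase that starts leukotriene synthesis, stood at -2.22 with A. fumigatus, -1.17 with P. notatum and -0.02 with A. alternata, and its partner ALOX5AP at -1.37, -1.34 and -0.83. Under normexp ALOX5AP stood at -0.58 with A. fumigatus and -0.95 with P. notatum, under 2-fold. The cyclooxygenase gene PTGS1 stood at 2.09, 0.95 and 0.34 and PTGS2 at 1.02, 0.94 and 1.14. With the mean over probes PTGS1 stood at 1.34 with A. fumigatus. The prostanoid and leukotriene list as a whole had medians of 0.12, 0.18 and -0.02. The small heat shock genes HSPB8 (-2.54, -1.73 and -1.01) and CRYAB (-2.12, -2.17 and -1.42) were lower with every extract, and with A. fumigatus stood at -1.71 and -1.45 under normexp. Of 5 measured HSPB genes 3 were at least 2-fold lower and 1 higher with A. fumigatus, and the heat shock list had medians of -0.22, -0.08 and -0.17. GDF15, a stress cytokine on the p53 list, was higher with every extract (3.09, 1.98 and 1.39), and the p53 list had medians of -0.02, -0.07 and 0.23. Endoplasmic reticulum stress genes had medians of 0.33, 0.27 and 0.19, at the 99.86th, 99.93rd and 99.96th percentiles of random lists.

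The metallothioneins, close relatives that probes may not tell apart, had a median of -0.43 with P. notatum at the 0th percentile, with MT1M at -1.32, against -0.02 and 0.05 with A. fumigatus and A. alternata. The settings tried left the P. notatum value between -0.43 and -0.37. The TGF-beta list had medians of -0.03, 0.06 and 0.09. Within it ID2 (2.60 and 2.57 with A. fumigatus and P. notatum) and THBS1 (-1.62 and -1.49) stood far apart, with ID2 at 1.392 and 1.103 under normexp. Toll-like receptor TLR6 was higher with A. fumigatus (2.40) and P. notatum (2.16) from a vehicle signal of 32.2, and stood at 1.32 and 1.04 with the mean over probes. The receptor list had medians of -0.28, 0.09 and 0.21, which turned to 0.44 with A. fumigatus with no filter on dim probes and to -0.12 with A. alternata with a signal of at least 100. Among junction genes CLDN3 stood at 1.82, 1.07 and 1.01 and CLDN1 at -1.43, -0.82 and -0.28, with list medians of 0.20, -0.01 and -0.09. The A. fumigatus median, at the 98.1th percentile, fell to the 90.6th under normexp and to the 57.9th with a signal of at least 100, at a median of 0.0065. With the mean over probes CLDN3 stood at 0.49 with P. notatum and 0.58 with A. alternata, under 2-fold. Ciliated cell markers had medians of -0.49, -0.50 and -0.02 over 4, 5 and 5 measured genes. The P. notatum value lay at the 2.045th percentile, against the 3.66th under normexp and the 3.36th with a signal of at least 100. Leukocyte markers had medians of 0.87, 0.16 and 0.35 over 6 genes and fibroblast and endothelial markers -0.51, -0.09 and 0.16 over 6. With no filter on dim probes the A. fumigatus medians of the ciliated and fibroblast lists turned to 0.31 and 0.998. The 16 reference genes had medians of 0.12, -0.01 and 0.03.

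The pregnancy-specific glycoprotein genes, picked after their values were seen, were all 6 at least 2-fold lower with A. alternata among those measured (median -1.93). They were lower with the other extracts too. PSG1, PSG4, PSG6, PSG7 and PSG9 were well above background with vehicle and not with A. fumigatus or P. notatum, and PSG8 stood at -3.49 with P. notatum. PSG11 went the other way, with a signal of 2.88 with vehicle, not well above background, and 26.1 with P. notatum, well above it. The members are near-identical in sequence, so the 6 values need not be independent. With A. alternata PSG1, PSG4, PSG7 and PSG9 had signals of 21.2, 25.3, 23.7 and 23.3, near background. Under normexp PSG4 stood at -0.97 with this extract, under 2-fold, and PSG9 at -1.04.

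Genes seen after the fact among those with a lower bound included the matrix protease gene MMP13, at least 13.8-fold higher with A. fumigatus and at least 10.8-fold with P. notatum. EGR3 was at least 18.5-fold higher with A. fumigatus. CXCL11, a T cell chemokine, was at least 7.08-fold higher with A. alternata and TLR10 at least 7.66-fold higher. CYP1A1 was at least 24.2-fold higher with A. fumigatus, 9.95-fold with P. notatum and 26.3-fold with A. alternata.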
